A study of Caenorhabditis elegans with 12 samples.

How the data were processed

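Messenger RNA of whole Caenorhabditis elegans was measured in 12 libraries, 3 each of worms fed a control diet, desiccated thymus, a cytoplasmic thymus extract or a nuclear thymus extract. Per the labels' protocols, total RNA was enriched with oligo(dT) beads, made into libraries with a kit for Illumina sequencing and read in pairs of 150 bases. The molecule field of the labels says nuclear RNA, which differs from the extraction protocol. The deposited table holds whole-number read counts per gene, which the authors made with the tools named in the submitters' processing notes: Trimmomatic, STAR, featureCounts and DESeq2, without versions. The genome build was taken from the RefSeq chromosome accessions in the table's own columns, which are those of WBcel235. Strand setting and treatment of reads with several matches were not given in the sources used here, so values of near-identical copies and of overlapping genes are uncertain.

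Groups and replicate numbers came from the sample titles. Count columns carry initials of the diets (TD, TCF and TNF) with a replicate number, and each was given to the only title with those initials and that number, which is an inference from names. Of 46929 genes in the table, 46925 were matched by identifier to a RefSeq gene table of WBcel235, where 98.6% of gene starts were equal, and 20979 had no count in any library. Library totals, in units of 1e6 counts, ran from 23.1 to 33.4. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Pairs of replicates differed by more than sampling noise, with chi-square per degree of freedom of 5.85 to 30.9 outside desiccated thymus replicate 3 and 203 to 321 in its 2 pairs, so all 12 were kept as separate samples.

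Genes were kept by edgeR's filterByExpr with a minimum count of 10 by group, which left 14610. Libraries were scaled by TMM factors, and 1 model with a mean per group was fitted to all 12 libraries with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust, 8 residual degrees of freedom, biological coefficient of variation 12.7%). Each comparison was tested two-sided with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05 and no fold threshold. Every single-gene adjusted p in the text comes from this test unless another tool is named. Log2 fold changes have standard errors from the same fit, and CPM values use TMM-scaled totals. An exact permutation test of 3 libraries against 3 cannot give a two-sided p below 0.1.

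For gene lists, 54 lists of tissue markers, stress responses, metabolic pathways and gene families were written down with 2943 members, of which 2217 were tested. Each list was compared with all other genes by camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the 54 lists. With a correlation estimated from the data, no list passed in any comparison, and the lowest adjusted p against the control was 0.116. With the preset, 23, 27 and 23 lists passed for desiccated thymus, the cytoplasmic extract and the nuclear extract against the control, and 19 between the 2 extracts. Members that passed were counted over all tested genes and adjusted over the list alone.

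Genes named singly had an adjusted p under 0.05, no overlap between the 3 libraries of each group, and a mean of at least 5 CPM in the higher group. Named were the 8 higher and 8 lower genes of largest change with a gene name, and the 2 higher and 2 lower genes of smallest p, for each comparison with the control and between the extracts, and the 3 higher and 3 lower of largest change for the other comparisons. From each described list, up to 4 passing members of largest change could be named, without the conditions on overlap and CPM, so some of these are low and changed more than the genes named singly. The groups, tests, lists and naming rule were chosen before the data were examined.

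Equal replicate numbers were checked for pairing by correlating the deviations from the group means across genes. Same-numbered libraries of the control and desiccated thymus (0.149, 0.471 and 0.199), of the control and the nuclear extract (0.383, 0.669 and 0.33) and of desiccated thymus and the nuclear extract (0.254, 0.473 and 0.197) deviated together, so these comparisons were also read with the number as a block. Libraries of the cytoplasmic extract deviated together with the others for replicates 2 and 3 but not for replicate 1. The pairing comes from these values only, since the labels name no shared batch.

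The scripts were tested on simulated data drawn from a negative binomial with the gene means, dispersions and library totals of this data set. For the nuclear extract against the control, with 200 of 14610 genes changed, 22.0% of genes changed 1.25-fold, 46.7% at 1.5-fold, 65.3% at 2-fold and 82.0% at 4-fold were recovered, with 6 to 8 false calls in 3 draws. With no change simulated in the cytoplasmic extract against the control, 0 to 3 genes and 0 to 1 lists were called. The simulation drew each gene independently and so leaves out the correlation between genes, on which list tests depend. Other splits of the real libraries of this comparison gave up to 18 lists, so the simulated number is no false call rate for lists. Overlap between diets was set beside 20 simulations of unchanged groups that share simulated control libraries.

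Alternatives were RLE size factors, library totals without TMM, no low-count filter, a filter of 1 CPM in 3 libraries, the legacy quasi-likelihood fit, the replicate block, DESeq2 1.42.0, fits of 2 groups only, an absolute log2 fold of at least 1, each library left out in turn, and for lists an estimated correlation and fry. These were set down before the counts were opened. Removal of ribosomal RNA genes, thinning to the lowest total and a covariate of sperm genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9.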

Results

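Messenger RNA of whole Caenorhabditis elegans was sequenced in 12 libraries, 3 for each of 4 diets. The diets were a control, desiccated bovine thymus, a cytoplasmic extract of bovine thymus and a nuclear extract of bovine thymus, fed from day 1 of adulthood. The age at collection was not given in the sources used here. Deposited read counts per library, in units of 1e6, totalled between 23.1, in nuclear extract replicate 3, and 33.4, in desiccated thymus replicate 1, and 14610 genes had enough counts to be tested. Ribosomal RNA genes took 0.393% to 2.27% of the counts in 11 libraries and 14.7% in desiccated thymus replicate 3. The series asks how the transcriptome of adult worms differs between these diets.

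Across all 4 diets together, 1121 of 14610 genes changed (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The count was 731 without nuclear extract replicate 2 and 699 without nuclear extract replicate 3. Against the control, the nuclear extract changed 1943 genes, desiccated thymus 565 and the cytoplasmic extract 104.

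**Figure D1:**
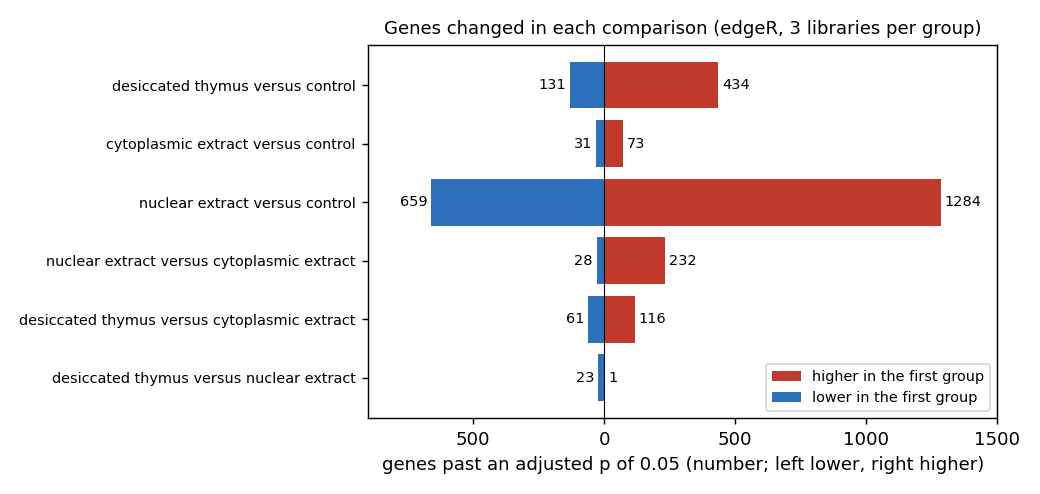
Number of genes past an adjusted p of 0.05 in each comparison, with genes higher in the first-named group to the right and genes lower in it to the left (3 libraries per group). The nuclear extract against the control gave 1284 higher and 659 lower genes, and the cytoplasmic extract against the control 73 higher and 31 lower.

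Desiccated thymus against the control asks which genes differ after feeding the dried gland. Some heat-inducible chaperone genes fell with desiccated thymus, and some intestinal, nutrient transporter and C-type lectin genes rose, while no gene list passed camera with an estimated correlation. The heat-inducible chaperone hsp-70 averaged 296 ± 57.0 CPM (counts scaled to a library total of 1e6; SD, n = 3) in the control and 86.2 ± 19.6 with desiccated thymus. The RNA of aip-1, which encodes an arsenite-inducible zinc finger protein that associates with the proteasome, fell from 127 ± 4.73 to 66.9 ± 3.88 CPM. Of all tested genes, 434 rose and 131 fell, and 146 of the 565 changed at least 2-fold.

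Among lists of genes fixed in advance, 9 of 17 cytosolic heat shock genes fell with desiccated thymus and none rose, and 13 fell when adjusted over the list alone. The list's median log2 fold change was -0.24 (camera, adjusted p = 3.72e-10, and adjusted p = 0.134 with an estimated correlation). Besides hsp-70, the small heat shock genes hsp-16.41 (-1.59) and hsp-16.2 (-1.45) and the Hsp70 family gene F44E5.4 (-1.38) led it. The call of hsp-16.41 was lost without desiccated thymus replicate 2 (edgeR adjusted p = 0.0519) and that of hsp-16.2 without desiccated thymus replicate 1 (0.0511). F44E5.4 has a near-identical copy, so its reads may be shared and its value is uncertain. Of 19 intestine markers, 6 rose and none fell (6 when adjusted over the list alone), with 3 higher without desiccated thymus replicate 2 (camera, adjusted p = 5.69e-05, and adjusted p = 0.134 with an estimated correlation). They included the peptide transporter gene pept-1 (1.15), the ABC transporter gene pgp-1 (1.26) and elt-2 (0.79), which encodes a GATA factor of intestinal genes. Of 25 nucleoside and nutrient transporter genes, 7 rose and none fell (9 when adjusted over the list alone), led by the amino acid transporter genes aat-7 (2.37) and aat-6 (1.21), with 4 higher without desiccated thymus replicate 2 (camera, adjusted p = 0.000491, and adjusted p = 0.134 with an estimated correlation).

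Of 113 C-type lectin genes, 12 rose and none fell with desiccated thymus, and 19 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 3.52e-06, and adjusted p = 0.116 with an estimated correlation). C-type lectins are carbohydrate-binding proteins, many of them secreted in the gut, and clec-165 rose by 1.50. The count of higher C-type lectins was 7 without control replicate 1, 2 or 3, 6 without desiccated thymus replicate 2 and 4 without desiccated thymus replicate 3. Of 55 cytochrome P450 genes, 5 rose and none fell (6 when adjusted over the list alone), led by cyp-29A4 (1.24) and cyp-13A2 (1.00; camera, adjusted p = 0.0111, and adjusted p = 0.539 with an estimated correlation). Of 35 genes of fatty acid breakdown and fasting, 5 rose and none fell (7 rose and 4 fell when adjusted over the list alone), among them the carnitine palmitoyltransferase gene cpt-5 (1.11) and the acyl-CoA oxidase gene acox-1.1 (0.68; camera, adjusted p = 0.371). That count was 3 without control replicate 1 or 2 or any library of desiccated thymus, and 3 with scaling by library totals only.

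Of 140 cuticle collagen genes, 5 rose and none fell with desiccated thymus (5 when adjusted over the list alone), and 8 rose with the replicate number as a block. Over all tested genes 2.97% rose, so the count of 5 lies near the share over all genes. The count was 3 without desiccated thymus replicate 3, the library with the high ribosomal RNA share, and the list's median was 0.58 (camera, adjusted p = 2.57e-05, and adjusted p = 0.614 with an estimated correlation). Higher members included col-96 (0.92), col-143 (0.61) and col-101 (0.53). None of 23 neuron markers passed edgeR's test over all genes (2 at an unadjusted p under 0.05, none with DESeq2). The list had a camera adjusted p of 0.0651, or 0.0434 with the replicate number as a block, and 0.662 with an estimated correlation and no block. Of 33 proteasome genes, 3 fell and none rose (12 fell when adjusted over the list alone), with a median of -0.09 (camera, adjusted p = 3.72e-10, and adjusted p = 0.457 with an estimated correlation). The proteasome count was 0 without desiccated thymus replicate 1, 1 without desiccated thymus replicate 3, 0 with scaling by library totals only and 6 with RLE size factors.

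Single genes with the smallest p in this comparison were aip-1 (CELE_F58E10.4, chromosome V, 14012333 to 14013644, WBcel235), with a log2 fold change of -0.92 (SE 0.0550, adjusted p = 2.83e-07, edgeR's quasi-likelihood test), and Y94H6A.10 (chromosome IV, 2710121 to 2710666), with -0.87 (SE 0.0437, adjusted p = 4.38e-08). Both were lower in 3 of 3 libraries of desiccated thymus than in any control. Lack of overlap was a condition for naming, and 20.2% of all tested genes had none here. T05A12.4 (chromosome IV, 6887948 to 6897783) rose by 0.89 (SE 0.0674, adjusted p = 5.31e-06), and acp-6, an acid phosphatase gene, by 0.65. The largest increases among genes of at least 5 CPM were in clec-174 (4.62), ugt-48 (1.81), srlf-34 (1.77), the nuclear hormone receptor gene nhr-43 (1.62), the carboxylesterase family gene cest-10 (1.62), fozi-1 (1.58), the tyrosinase family gene tyr-6 (1.41) and drd-1 (1.37). The largest decreases besides heat shock genes were in arl-3 (-1.75), which encodes a small GTPase of cilia, pugs-2 (-1.51), the furin-type protease gene kpc-1 (-1.34), the cholesterol transport gene ncr-1 (-1.31) and lact-4 (-1.02).

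The call of clec-174 was lost without desiccated thymus replicate 3 (adjusted p = 0.0987) or without control replicate 1 (0.104), 2 (0.107) or 3 (0.087). The call of pugs-2 was lost without control replicate 2 (0.0725) or desiccated thymus replicate 2 (0.0895) or 3 (0.0892), and that of ncr-1 without desiccated thymus replicate 2 (0.0529) or 3 (0.0584). The number of changed genes against the control was 375 without control replicate 2, and 328, 322 and 302 without desiccated thymus replicates 1, 2 and 3. DESeq2 called 871 genes. When only these 2 groups were fitted, edgeR called 327. There the calls of hsp-70 (adjusted p = 0.0503), clec-174 (0.181), pugs-2 (0.113) and ncr-1 (0.0857) were lost.

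The cytoplasmic extract against the control asks which genes differ after feeding the cytoplasmic fraction. The RNA of aip-1 averaged 77.3 ± 4.44 CPM with the cytoplasmic extract against 127 ± 4.73 in the control (SD, n = 3). The genes T05A12.4, srlf-34 and cest-10 rose, and lec-11 and lec-10, genes of galectins that bind galactosides, fell. Of all tested genes, 73 rose and 31 fell, and 19 of the 104 changed at least 2-fold.

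With the cytoplasmic extract, 3 of 17 cytosolic heat shock genes fell and none rose, and 9 fell when adjusted over the list alone. The gene hsp-70 did not pass over all genes, although it averaged 119 ± 30.4 CPM against 296 ± 57.0 in the control (SD, n = 3). The list's median was -0.18 (camera, adjusted p = 1.96e-07, and adjusted p = 0.23 with an estimated correlation), and the co-chaperone gene dnj-13 fell by 0.31. The count was 1 without cytoplasmic extract replicate 1, where the call of F44E5.4 (-1.41) was lost (edgeR adjusted p = 0.0669). F44E5.5 (-1.13), the near-identical copy of F44E5.4, is uncertain for the same reason and lost its call without control replicate 2 (0.0985) or 3 (0.0627) or without cytoplasmic extract replicate 1 (0.136), 2 (0.0636) or 3 (0.0955). None of 33 proteasome genes passed over all genes tested by edgeR (15 lower at an unadjusted p under 0.05, 5 lower with DESeq2, and 13 when adjusted over the list alone), with a median of -0.09 (camera, adjusted p = 8.4e-10, and adjusted p = 0.368 with an estimated correlation). Of 39 glutathione S-transferase genes, only gstk-1 passed (5 fell when adjusted over the list alone), with a median of -0.20 (camera, adjusted p = 0.000356, and adjusted p = 0.171 with an estimated correlation). Of 140 cuticle collagen genes, only col-143 rose (0.34), or 3 when adjusted over the list alone (camera, adjusted p = 5.61e-06, and adjusted p = 0.515 with an estimated correlation), and 3 rose without control replicate 2. Over all 14610 tested genes 73 rose, a similar share to 1 of 140.

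The genes with the smallest p were T05A12.4, with a log2 fold change of 1.03 (SE 0.0672, adjusted p = 1.86e-06, edgeR's quasi-likelihood test), the pseudogene Y102A5C.5 (2.20, SE 0.165, adjusted p = 7.86e-06), aip-1 (-0.71, SE 0.0546, adjusted p = 7.86e-06) and Y94H6A.10 (-0.45, SE 0.0433, adjusted p = 0.000104). Each of the 3 libraries lay beyond all 3 controls for these genes, which was a condition for naming and held for 17.7% of all tested genes. The largest increases were in srlf-34 (1.63), cest-10 (1.34), pgph-3 (1.22), the bestrophin channel gene best-1 (1.06), the glutamate transporter gene glt-5 (1.02), the ectonucleotide phosphodiesterase gene enpp-1 (0.89), the molting protease gene nas-37 (0.89) and the organic anion transporter gene oat-1 (0.89). The largest decreases were in the cilium gene dyf-3 (-1.03), the galectin genes lec-11 (-0.80), lec-10 (-0.48) and lec-6 (-0.45), the diacylglycerol acyltransferase gene dgat-2 (-0.68), ttm-5 (-0.59) and gstk-1 (-0.43).

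Calls lost when 1 library was left out in the comparison of the cytoplasmic extract with the control were those of lec-6 (any of the 6 libraries, adjusted p 0.0509 to 0.102), best-1 (any of the 6, 0.0523 to 0.15), dgat-2 (any but control replicate 1, 0.0841 to 0.195), ttm-5 (any but control replicate 1, 0.0705 to 0.206) and gstk-1 (any but control replicate 1, 0.101 to 0.172). The call of pgph-3 was lost without control replicate 1 or 3 or cytoplasmic extract replicate 2 or 3 (0.0593 to 0.0843), that of oat-1 without control replicate 2 or cytoplasmic extract replicate 1 or 3 (0.0672 to 0.0955) and that of dyf-3 without cytoplasmic extract replicate 1 (0.0672) or 3 (0.0632). The number of changed genes was 51 without control replicate 2, 37 without cytoplasmic extract replicate 1, 45 without cytoplasmic extract replicate 3 and 342 with DESeq2. It was 46 when only these 2 groups were fitted. That fit lost the calls of lec-11 (adjusted p = 0.0522), enpp-1 (0.0798), oat-1 (0.0798), dyf-3 (0.0795), pgph-3 (0.0833), dgat-2 (0.17), ttm-5 (0.144) and gstk-1 (0.108). With scaling by library totals only, 98 genes rose and 20 fell (83.1% higher, against 70.2% with TMM).

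The nuclear extract against the control asks which genes differ after feeding the nuclear fraction. Some genes of the intestine, the cuticle, nutrient transporters and UDP-glucuronosyltransferases rose with the nuclear extract, and some heat-inducible chaperone, oocyte and eggshell genes fell, while no gene list passed camera with an estimated correlation. The ABC transporter gene pgp-1 rose from 3.91 ± 0.230 to 16.5 CPM, and the cuticle collagen gene col-143 from 71.2 ± 4.47 to 163 CPM (means, SD of the control, n = 3). The chaperone gene hsp-70 fell from 296 ± 57.0 to 68.7 ± 9.97 CPM. Of all tested genes, 1284 rose and 659 fell, and 389 of the 1943 changed at least 2-fold.

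Of 19 intestine markers, 9 rose and 1 fell with the nuclear extract (11 and 1 when adjusted over the list alone), with a median log2 fold change of 0.33 (camera, adjusted p = 1.97e-05, and adjusted p = 0.147 with an estimated correlation). Besides pgp-1 (2.08), they included pept-1 (1.86), the heme transporter gene hrg-4 (1.77) and the acid phosphatase gene pho-1 (1.00). Of 25 nucleoside and nutrient transporter genes, 12 rose and 1 fell (13 and 3 when adjusted over the list alone), led by aat-7 (2.26; camera, adjusted p = 0.000597, and adjusted p = 0.156 with an estimated correlation). Of 113 C-type lectin genes, 24 rose and none fell (38 and 1 when adjusted over the list alone), with clec-5 at 1.35 and a count of 15 without control replicate 1 (camera, adjusted p = 1.97e-05, and adjusted p = 0.147 with an estimated correlation). Of 58 UDP-glucuronosyltransferase genes, whose enzymes conjugate small molecules for excretion, 17 rose and 1 fell (18 and 3 when adjusted over the list alone). They were led by ugt-48 (2.00), ugt-31 (1.37) and ugt-17 (0.99), and 11 rose without nuclear extract replicate 3 (camera, adjusted p = 0.000146, and adjusted p = 0.287 with an estimated correlation). Of 25 genes of fatty acid synthesis and desaturation, 10 rose and 2 fell (11 and 2 when adjusted over the list alone). The fatty acid elongase genes elo-6 (0.76) and elo-5 (0.60) and the desaturase gene fat-3 (0.60) were among the higher ones (camera, adjusted p = 0.00421, and adjusted p = 0.147 with an estimated correlation).

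Of 140 cuticle collagen genes, 22 rose and none fell with the nuclear extract (24 when adjusted over the list alone), with a median of 1.08 (camera, adjusted p = 3.49e-07, and adjusted p = 0.457 with an estimated correlation). The mean log2 CPM of the list overlapped between libraries, from -0.189 to 1.75 in the control and 1.13 to 2.89 with the nuclear extract. Of the 140 genes, 48 averaged under 2 CPM. The count of higher collagens was 14 without control replicate 1 and 14 without nuclear extract replicate 3, and members included col-117 (2.93) and dpy-7 (1.84). Of 19 hypodermis markers, 8 rose and 1 fell (12 and 2 when adjusted over the list alone), among them grd-10 (2.30), with 5 higher without control replicate 1 or 2 or nuclear extract replicate 2 or 3 (camera, adjusted p = 0.00109, and adjusted p = 0.399 with an estimated correlation). Of 69 sperm genes, 10 rose and none fell (11 when adjusted over the list alone), with 5 without control replicate 1 and 6 without nuclear extract replicate 3 (camera, adjusted p = 0.00421, and adjusted p = 0.677 with an estimated correlation). Of the 10, 9 are nspc genes and 1 is ssp-37, and none of 27 msp genes (major sperm proteins) passed, although their median was 0.46. In a test added after the data were seen, the 55 sperm genes other than nspc had an unadjusted camera p of 0.234. That split was made by the calls, so it only restates that the call of the list rests on nspc genes. They were led by nspc-18 (1.64), nspc-19 (1.50), nspc-17 (1.45) and nspc-16 (0.93), neighbouring members of a family of similar genes whose reads the counting may have split, so that each single value is uncertain.

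Sperm and cuticle collagen scores (mean log2 CPM of each list) varied together between libraries of the same diet. The sperm score is carried by genes near the floor, since 50 of 69 members averaged under 2 CPM and 38 of these had no count in at least 1 library. Of the 12 members at 5 CPM or more, mostly nspc genes, 9 correlated negatively with the score, and the mean of the 12 had an r of only 0.339 with the collagen deviations. Level and gene family are mixed in that value, since ssq-1, at 5.3 CPM, had an r of 0.953 with the score. Over 12 libraries, the deviations of the sperm and collagen scores from the group means had a Pearson's r of 0.891 (permutation p = 0.00831, 0.0415 adjusted over 5 relations). Spearman's rho was 0.86 (permutation p = 0.00708), and r was 0.826 without control replicate 2 and nuclear extract replicate 2, the farthest from the median. These p treat the libraries of a diet as exchangeable, although sperm deviations followed the replicate number, which held 0.762 of their sum of squares (exact p = 0.0139 over 1296 orders within diets) against 0.55 for collagens (exact p = 0.125). With the means of the replicate numbers removed, r was 0.884, and whole sets of equal number have only 6 orders, so no p below 0.167 is possible for them. With the sperm score as a covariate, chosen after the data were seen, 24 collagens rose and 1 fell with the nuclear extract.

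**Figure D2:**
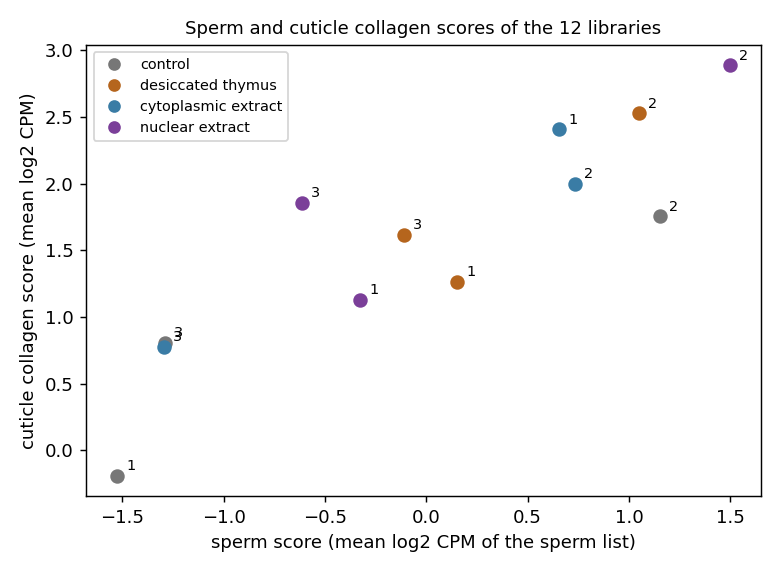
Sperm score against cuticle collagen score of each library (mean log2 CPM of the list), coloured by diet and numbered by replicate. Libraries of 1 diet spread along a shared line, and the deviations from the group means had a Pearson's r of 0.891 over 12 libraries.

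Of 17 cytosolic heat shock genes, 8 fell and none rose with the nuclear extract (8 when adjusted over the list alone), with a median of -0.25 (camera, adjusted p = 3.99e-06, and adjusted p = 0.285 with an estimated correlation). Members were hsp-70 (-2.11), hsp-16.41 (-1.67), F44E5.5 (-1.58) and hsp-16.2 (-1.49). Of 26 oocyte and eggshell genes, 12 fell and none rose (17 when adjusted over the list alone), by small amounts with a median of -0.12 (camera, adjusted p = 3.49e-07, and adjusted p = 0.399 with an estimated correlation). The eggshell gene cpg-1 fell by 0.26. The count of lower oocyte and eggshell genes was 7 without nuclear extract replicate 2, 6 without nuclear extract replicate 3, and 1 with scaling by library totals only. Of 36 cell cycle and DNA replication genes, 10 fell and none rose (12 when adjusted over the list alone; camera, adjusted p = 6.31e-07, and adjusted p = 0.367 with an estimated correlation). The count was 3, 5, 1 and 0 without control replicate 1, control replicate 2, nuclear extract replicate 2 and nuclear extract replicate 3, and 0 with scaling by library totals only. None of 20 body wall muscle markers passed edgeR's test with the nuclear extract (2 higher at an unadjusted p under 0.05, 1 higher with DESeq2). The list had a camera adjusted p of 0.0813, or 0.0453 with the replicate number as a block, and 0.731 with an estimated correlation and no block.

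**Figure D3:**
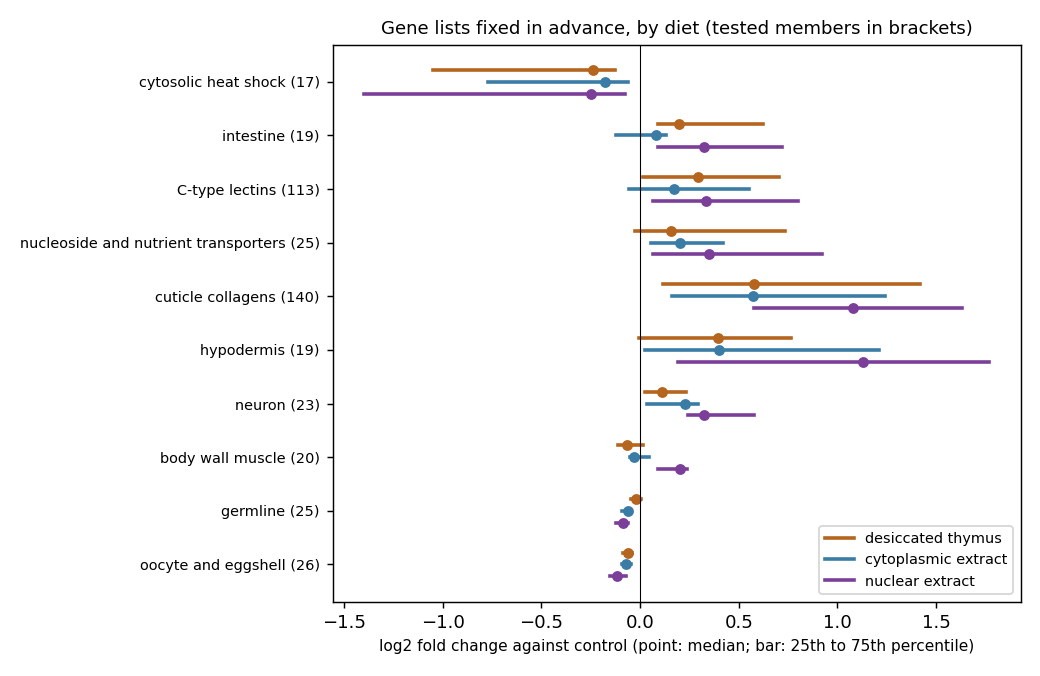
Median log2 fold change against the control (points) and the range from the 25th to the 75th percentile (bars) over the tested members of 10 gene lists, for each diet. The heat shock median lay below 0 with all 3 diets (-0.24, -0.18 and -0.25), and with the nuclear extract the hypodermis and collagen medians were 1.13 and 1.08. Bars show the spread over genes, not libraries, and collagen scores of single libraries overlapped between the nuclear extract and the control.

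The smallest p in this comparison belonged to col-143 (CELE_T15B7.3, chromosome V, 6835635 to 6836704), with a log2 fold change of 1.19 (SE 0.0546, adjusted p = 1.24e-08, edgeR's quasi-likelihood test). pgp-1 (CELE_K08E7.9, chromosome IV, 12591695 to 12599169) was next among the higher genes, with 2.08 (SE 0.129, adjusted p = 2.29e-07). Lower genes with the smallest p were Y94H6A.10 (-0.83, SE 0.0437, adjusted p = 4.91e-08) and aip-1 (-0.96, SE 0.0551, adjusted p = 1.02e-07). All 3 libraries of the nuclear extract lay beyond all 3 controls for these genes. That was a condition for naming and held for 33.3% of all tested genes. Other large increases were in oac-32 (2.31), the collagen gene col-41 (1.96), cest-10 (1.96), acn-1 (1.84), which is needed for molting, and gcsh-1 (1.81), and other large decreases in arl-3 (-1.38), pugs-2 (-1.30), the glycogenin gene gyg-1 (-1.04), the tetraspanin gene tsp-2 (-1.03) and ncr-1 (-1.03).

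The call of oac-32 was lost without any of the 6 libraries in turn (adjusted p 0.0695 to 0.125) and with the replicate block (0.0533), and that of col-41 without control replicate 2 or any nuclear extract library (0.0516 to 0.112), with the block (0.0624) and with DESeq2 (0.102). The call of gyg-1 was lost without any nuclear extract library (0.0786 to 0.0949) and with the block (0.0598), that of pugs-2 without control replicate 2 or nuclear extract replicate 1 or 3 (0.0571 to 0.0707) and that of ncr-1 without nuclear extract replicate 3 (0.0645). The number of changed genes was 1122 without control replicate 1, 1026 without nuclear extract replicate 2, 885 without nuclear extract replicate 3 and 1114 when only these 2 groups were fitted. The last of these lost the calls of col-41 (adjusted p = 0.0577), pugs-2 (0.0732), gyg-1 (0.117) and ncr-1 (0.0929). With scaling by library totals only, 92.5% of the 1355 changed genes were higher, against 66.1% with TMM, and the median over all genes moved by 0.04.

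Comparing the nuclear with the cytoplasmic extract asks how the 2 cell fractions differ. Some intestinal and collagen genes were higher with the nuclear extract than with the cytoplasmic extract, while no gene list passed camera with an estimated correlation. The gene pgp-1 averaged 16.5 against 5.67 CPM and pho-1 15.1 against 6.40 CPM (means, n = 3). Of all tested genes, 232 were higher and 28 lower with the nuclear extract, and 39 of the 260 differed at least 2-fold. Of 19 intestine markers, 7 were higher and none lower (10 when adjusted over the list alone), with 4 without cytoplasmic extract replicate 2 or 3 or nuclear extract replicate 1 (camera, adjusted p = 6.77e-09, and adjusted p = 0.0711 with an estimated correlation). Of 140 cuticle collagen genes, 7 were higher and none lower (12 when adjusted over the list alone), led by col-143 (0.86) and col-101 (0.81; camera, adjusted p = 0.00426, and adjusted p = 0.694 with an estimated correlation). Of 39 glutathione S-transferase genes, gst-13 (1.11) and gst-26 (0.83) were higher (4 when adjusted over the list alone; camera, adjusted p = 0.0154, and adjusted p = 0.21 with an estimated correlation). The purine salvage gene hprt-1 (0.37) and the pyrimidine breakdown gene dpyd-1 (0.47) were among 3 of 32 purine and pyrimidine genes that were higher (5 when adjusted over the list alone; camera, adjusted p = 0.295). No cytosolic heat shock gene passed edgeR's test between the extracts over all genes (3 lower at an unadjusted p under 0.05, 1 lower with DESeq2).

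Among single genes, pgp-1 (1.54, SE 0.122, adjusted p = 1.43e-05, edgeR's quasi-likelihood test) and col-143 (SE 0.0541, adjusted p = 1.27e-06) had the smallest p of the higher genes. The other higher ones were the scavenger receptor gene scav-4 (1.27), let-383 (1.25), pho-1 (1.24), pept-1 (1.18), aat-6 (1.11) and ugt-48 (1.08). Y94H6A.10 (-0.37, SE 0.0435, adjusted p = 0.000493) and ZK669.3 (-0.52, SE 0.0883, adjusted p = 0.00745) had the smallest p of the lower genes, and the other lower ones were fbxc-58 (-0.94), the ETS factor gene ets-7 (-0.71), ikb-1 (-0.51), mfb-1 (-0.48), wdfy-3 (-0.44), the pseudogene math-27 (-0.36), the ubiquitin-conjugating enzyme gene ubc-8 (-0.36) and fbxl-1 (-0.34). For each, the 3 libraries of one extract lay beyond the 3 of the other, which was a condition for naming and held for 22.6% of all tested genes.

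Of the lower genes, only wdfy-3, Y94H6A.10 and ZK669.3 kept their calls whichever library was left out. Calls were lost for mfb-1 without any of the 6 libraries in turn (adjusted p 0.0557 to 0.102), math-27 without any but cytoplasmic extract replicate 1 (0.0532 to 0.112), ubc-8 without any but nuclear extract replicate 2 (0.0601 to 0.17), fbxl-1 without any but cytoplasmic extract replicate 3 (0.0583 to 0.101), fbxc-58 without cytoplasmic extract replicate 2 or any nuclear extract library (0.0518 to 0.111), ets-7 without cytoplasmic extract replicate 1 or 3 or nuclear extract replicate 2 or 3 (0.0662 to 0.0902) and ikb-1 without replicate 1 or 2 of either extract (0.137 to 0.163). The call of aat-6 was lost without cytoplasmic extract replicate 2 (0.0739), and that of pept-1 when only these 2 groups were fitted (0.069). The number of changed genes was 132 and 88 without cytoplasmic extract replicates 1 and 2, 114, 164 and 135 without nuclear extract replicates 1, 2 and 3, and 474 with DESeq2.

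Desiccated thymus differed from the cytoplasmic extract in 177 genes, 116 higher and 61 lower, and 43 of them at least 2-fold. The RNA of acs-2, an acyl-CoA synthetase gene of fatty acid oxidation, averaged 40.1 CPM with desiccated thymus and 211 CPM with the cytoplasmic extract (119 ± 27.0 in the control; SD, n = 3), a log2 difference of -2.40 (SE 0.370, adjusted p = 0.0261, edgeR's quasi-likelihood test). That call was lost without any 1 of these libraries but cytoplasmic extract replicate 1 (adjusted p 0.0843 to 0.116). The genes glt-5 (-1.33) and T28F4.4 (-1.33) were lower, and Y47H9C.1 (3.46), F20G2.5 (1.76) and drd-1 (1.18) higher. The call of Y47H9C.1 was lost without any library but desiccated thymus replicate 2 (0.0884 to 0.156) or when only these 2 groups were fitted (0.198), and that of F20G2.5 without cytoplasmic extract replicate 2 (0.0545). The count of 177 became 58, 75 and 69 without desiccated thymus replicates 1, 2 and 3, and 91, 48 and 85 without cytoplasmic extract replicates 1, 2 and 3. With scaling by library totals only, 52 genes were higher and 90 lower (36.6% higher, against 65.5% with TMM), so the balance of directions in this comparison changed with the scaling. That scaling leaves out the TMM factors, of which desiccated thymus replicate 3, with 14.7% ribosomal RNA, had the lowest (0.874). Its ribosomal counts then lower the scaled values of its other genes. The median over all genes moved by -0.0704.

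Desiccated thymus differed from the nuclear extract in 24 genes, 1 higher and 23 lower, or 51 with the replicate number as a block. The histone methyltransferase gene set-25 (0.45, SE 0.0812, adjusted p = 0.0371, edgeR's quasi-likelihood test) was higher, and nspc-18 (-1.15), nspc-19 (-1.12) and nspc-17 (-1.04) were lower, with the uncertainty of similar copies. The calls of set-25 (adjusted p 0.0551 to 0.199), nspc-18 (0.0705 to 0.204) and nspc-19 (0.0609 to 0.157) were lost without any of the 6 libraries in turn, and that of nspc-17 without any but desiccated thymus replicate 2 (0.0666 to 0.199). The count was 8 and 11 without desiccated thymus replicates 1 and 3, 15, 6 and 15 without nuclear extract replicates 1, 2 and 3, and 258 with DESeq2. The balance of directions moved too. Without desiccated thymus replicate 2, 7 genes were higher and 14 lower, while scaling by library totals only gave 1 higher and 106 lower. There the median over all genes moved by -0.082, again with the low TMM factor of desiccated thymus replicate 3 left out.

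All 3 diets shared 56 changed genes against the control, 43 higher and 13 lower, and none went opposite ways. Among them were aip-1, Y94H6A.10, T05A12.4, col-143, srlf-34, cest-10, nas-37 and the desaturase gene fat-3. Without control replicate 2 the shared number was 36, and with DESeq2 it was 159. Desiccated thymus and the nuclear extract shared 372 higher and 83 lower genes, where independent lists would share 38.1 and 5.91. Desiccated thymus and the cytoplasmic extract shared 45 higher and 13 lower genes (independent lists 2.17 and 0.278), and the cytoplasmic and nuclear extracts 60 and 27 (6.42 and 1.40). In 20 simulations of unchanged groups, every library was drawn from the control means, and the 3 diets shared the simulated controls. No gene was shared there. Almost no gene is called when nothing changes, so that count is no baseline for the overlap. Across genes, which are not independent replicates, log2 fold changes correlated with r of 0.684 for desiccated thymus and the nuclear extract, against 0.495 simulated with shared controls and no effect. The covariance was 0.140 against 0.0935 simulated, a difference of 0.0467, and the differences were 0.0103 for desiccated thymus with the cytoplasmic extract and 0.0332 for the 2 extracts. The 3 controls could not be split into parts of at least 2 libraries, so part of the excess may come from the shared controls. The simulation drew libraries independently and leaves out the shared deviations of equal replicate numbers, so part may come from these too.

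**Figure D4:**
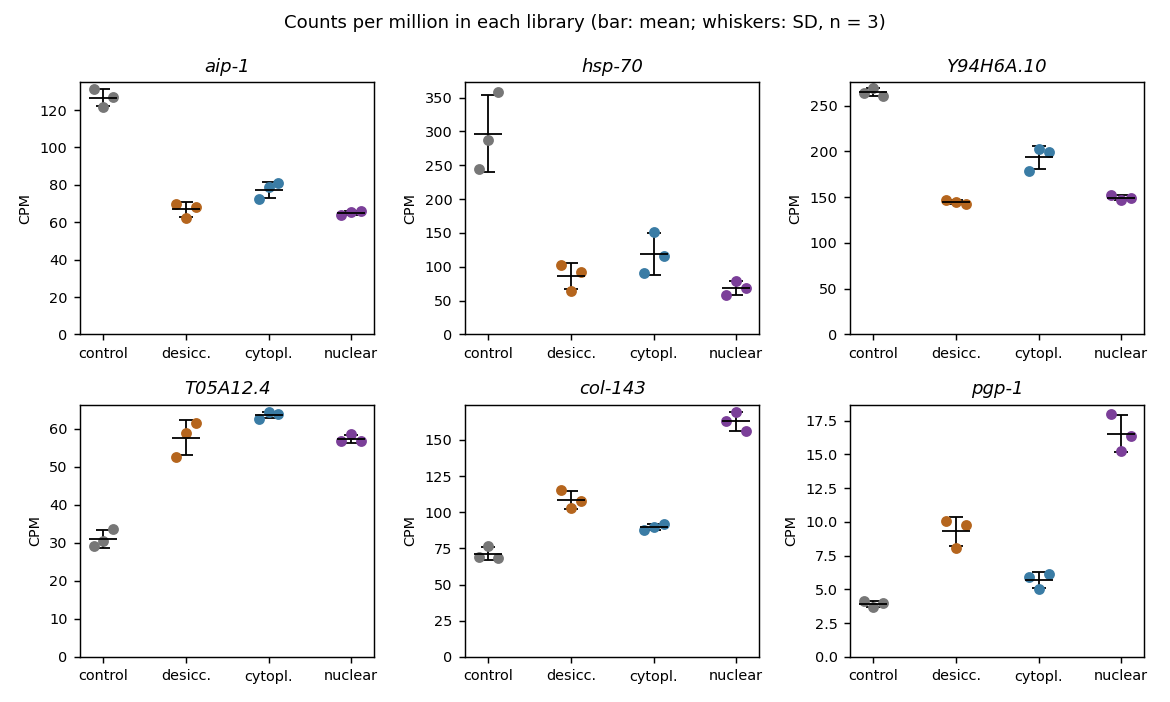
CPM of 6 genes in each library (points), with the mean (bar) and SD (whiskers, n = 3) of each diet. For aip-1 the means were 127 CPM in the control and 66.9, 77.3 and 65.0 CPM with desiccated thymus, the cytoplasmic extract and the nuclear extract, and for T05A12.4 they were 31.1, 57.7, 63.7 and 57.4 CPM.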

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

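Tests on the molt, on replicate numbers, on expression level and on sequencing depth along the sperm and collagen axis, on the share of somatic tissue, on the heat shock list with desiccated thymus and the cytoplasmic extract when a control is left out, and on Y94H6A.10 and aip-1 between diets were chosen only after the results were seen.

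Ribosomal RNA genes, which no comparison here is about, took 14.7% of the counts in desiccated thymus replicate 3, above the highest control at 1.52%. They took 1.72% in desiccated thymus replicate 2. They took 2.27% in cytoplasmic extract replicate 3.

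Within diets, sperm and cuticle collagen genes varied together between libraries (r = 0.891), but 50 of 69 sperm genes averaged under 2 CPM. The 12 at 5 CPM or more had an r of 0.339 with collagens. These 12 are mostly nspc genes, so that value cannot tell the expression level from the gene family. A set of libraries shared by equal replicate numbers may lie behind part of it and stays open, as the numbers held 0.762 of the sperm deviations (exact p = 0.0139) and 0.55 of the collagen deviations (exact p = 0.125), while r was 0.884 with their means removed. A differing share of animals near the larval-to-adult molt stays open too, with r = 0.575 between sperm and molting genes (permutation p = 0.159), and the age at collection was not given. Depth stays open with r = 0.299 (permutation p = 0.314, and r = 0.0712 without the 2 farthest libraries). A differing share of males cannot be told apart from these data, because only 4 of 10 male markers were tested, at a median of 0.548 CPM, and their r of 0.0165 (permutation p = 0.942) lies near the floor, which is why the bound set in advance was not taken as decisive.

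Many more genes passed the threshold with the nuclear extract than with the cytoplasmic extract, 1943 against 104, a ratio of 18.7, or 7.44 with DESeq2 (2544 against 342), 10.2 without control replicate 1 and 25.5 without control replicate 2. The ratio depends on the threshold, since at an unadjusted p under 0.05 (edgeR) the counts were 4420 and 1841. Compared directly, the extracts differed in 260 genes. Of the 1943 genes, 94.9% had the same sign with the cytoplasmic extract, against the same controls. Greater depth of the nuclear extract libraries is argued against by their totals. These ran from 23105256 to 25686496 counts, all below the cytoplasmic extract totals of 25761234 to 29239987. Thinning all libraries to the lowest total gave a ratio of 19.2, but with these totals it could hardly have lowered the ratio. Thinning therefore adds no test of depth. The sperm axis as the whole cause is argued against by a ratio of 11.9 with the sperm score as a covariate. A larger share of somatic tissue would raise somatic markers alike. The hypodermis median exceeded the body wall muscle median by 0.926 log2 units (1.13 against 0.20, permutation p = 5e-04). That p shuffled genes, which are not independent replicates. The 2 lists had the highest and the lowest somatic median and were picked after the data were seen. The test therefore cannot decide whether a somatic share is the whole cause. A larger somatic share, as the whole or part of the cause, stays open. The medians of neuron (0.32), intestine (0.33) and pharynx (0.52) markers were also higher, and those of germline (-0.09) and oocyte and eggshell genes (-0.12) lower. Only the hypodermis list, with quartiles of 0.19 and 1.77, stands apart. A response to the diets themselves remains a hypothesis, found and tested on the same data, and with 1 library left out the counts were 885 to 2090 for the nuclear and 37 to 117 for the cytoplasmic extract.

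The genes aip-1 and Y94H6A.10 passed as lower with all 3 diets, which share the same controls. So did 3 of 17 heat shock genes (dnj-13 and the similar copies F44E5.4 and F44E5.5), while hsp-70 did not pass with the cytoplasmic extract. The heat shock list had camera adjusted p of 0.134, 0.23 and 0.285 with an estimated correlation. An unusual control library is argued against for aip-1, whose highest adjusted p over the diets was 8.16e-05 (edgeR) with each control left out in turn, and for the heat shock list, of which at least 8 of 8 called members with the nuclear extract and 8 of 9 with desiccated thymus were kept whichever control was left out, but only 2 of 3 with the cytoplasmic extract, too few to tell. For Y94H6A.10, a shift of the control group alone is argued against by differences between diets, with an adjusted p of 0.000493 between the extracts and 0.000529 between desiccated thymus and the cytoplasmic extract, while aip-1 did not pass the same rule (0.03 and 0.0897) and stays open. For the heat shock list, a shift of all 3 controls cannot be told apart from an effect of the diets, since the lowest adjusted p of a member between diets was 0.186 and 3 libraries per group are few. Handling, stress or timing of the control group as a whole was therefore not excluded.

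Regrouping the libraries gave the following. For all 4 diets together, 1 of 100 drawn groupings, the real one, gave as many genes as 1121, with 144 in the highest other. The real grouping thus stood apart from these draws. They exchanged all 12 libraries freely, although libraries of equal number deviated together, so chance is not excluded by them. Regrouped fits, here and below, put libraries of different diets into 1 group. A difference between diets then widens the spread within groups and lowers the counts. Low gene counts in other groupings were therefore to be foreseen and are no false call rate. For each pair of groups 1 of 10 splits of the 6 libraries, the real one, gave as many, too few splits for a share under 0.05. The real split and the highest other gave 565 and 0 genes for desiccated thymus, 104 and 0 for the cytoplasmic extract and 1943 and 1 for the nuclear extract against the control. They gave 260 and 0 genes between the extracts, 177 and 0 between desiccated thymus and the cytoplasmic extract, and 24 and 4 between desiccated thymus and the nuclear extract. Lists passed camera in the real split and the highest other 23 and 20 times, 27 and 18 times and 23 and 18 times for the 3 diets in that order, and 19 and 16 times between the extracts. Between desiccated thymus and the cytoplasmic extract, a regrouping gave more lists (13) than the real split (9), and between desiccated thymus and the nuclear extract the numbers were 19 and 17, so list counts with the preset correlation say little about the diets. Among the 4 splits that part all 3 pairs of equal numbers, the other splits gave 0 genes for desiccated thymus and the nuclear extract against the control and for desiccated thymus against the nuclear extract, and the splits that part 1 pair gave up to 0, 1 and 4.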

How the results depend on the processing

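No named gene changed direction under any alternative. These genes were named because they had passed in the same data, so the lack of reversals is no test of their direction. Over 372 single-gene results, 5156 of 6307 values under alternatives stayed past the threshold, 1151 were lost and none reversed. Tests with ribosomal RNA genes removed, with thinned counts and with the sperm covariate were chosen after the data were seen. The cause was not tested for any change below. Counts of changed genes are incomplete, since in the simulation of the nuclear extract against the control 65.3% of genes changed 2-fold were recovered, and fewer at smaller changes.

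With DESeq2, counts of changed genes were 871 (desiccated thymus against control, 565 with edgeR), 342 (cytoplasmic extract, 104), 474 (nuclear against cytoplasmic extract, 260), 343 (desiccated thymus against cytoplasmic extract, 177), 258 (desiccated thymus against nuclear extract, 24), 1941 (all 4 diets, 1121) and 159 (shared by all 3 diets, 56). With 2 groups only they were 327, 46, 1114 (nuclear extract against control, 1943), 281 for desiccated thymus against the cytoplasmic extract and 180 for desiccated thymus against the nuclear extract. With an absolute log2 fold of at least 1 they were 146, 19, 389, 39, 43 and 5.

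Desiccated thymus against the nuclear extract, with 24 genes, also gave 107 with library totals only, 81 with no low-count filter, 41 with at least 1 CPM in 3 libraries, 38 with ribosomal RNA genes removed, 40 when thinned and 62 with the sperm covariate.

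Leaving out 1 library gave 302 to 497 genes for desiccated thymus, 37 to 117 for the cytoplasmic extract and 885 to 2090 for the nuclear extract against the control. It gave 88 to 177 between the extracts, 48 to 91 and 6 to 21 for desiccated thymus against the cytoplasmic and nuclear extracts, and 699 to 1122 over all diets. Lists passing ranged over 18 to 23, 22 to 29 and 24 to 26 for the 3 diets and 15 to 21 between the extracts, and shared genes over 36 to 69.

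With an estimated correlation, 0 lists passed camera in each comparison, against 23, 27, 23 and 19, and fry passed 8, 8, 27 and 5.

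With the replicate number as a block, changed genes numbered 591, 115 and 2080 against the control, 297 between the extracts, 175 and 51 for desiccated thymus against the cytoplasmic and nuclear extracts, and 1137 over all diets, and lists 24, 26, 24 and 19. For desiccated thymus and the nuclear extract against the control, the block changed no other list call than those of neuron and body wall muscle given above, and list calls between desiccated thymus and the nuclear extract were not run with it. For the cytoplasmic extract the pairing was mixed. Its replicate 1 correlated at -0.358 with the control, -0.353 with the nuclear extract and -0.242 with desiccated thymus. Its replicates 2 and 3 correlated at 0.458 and 0.349 with the control and 0.43 and 0.337 with the nuclear extract. With desiccated thymus they correlated at 0.249 and 0.321. For the cytoplasmic extract against the control, the block moved the calls of dgat-2 (0.0676), ttm-5 (0.0671) and gstk-1 (0.0501). It also moved that of the list propionate shunt and vitamin B12 (camera adjusted p from 0.0308 to 0.0559). Between the extracts it moved the lists neuron (camera adjusted p from 0.0636 to 0.0334) and respiratory chain (0.0431 to 0.0524).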

Other observations

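Gene families defined by their names, chosen after the data were seen, added groups beyond the lists above. Of 204 families with at least 8 tested members, 11 of 1632 tests of enrichment among changed genes passed (Fisher's exact test, one-sided, Benjamini-Hochberg). Of 12 galectin genes, 3 fell with the cytoplasmic extract (adjusted p = 0.00102), of which lec-6 lost its call without any 1 of the 6 libraries. Of 21 innexin genes, which encode gap junction channels, 8 rose with the nuclear extract (adjusted p = 0.0453), by between 0.33 for inx-12 and 1.11 for inx-6, and inx-17 rose by 0.62. Of 33 vps genes of vesicle sorting to the lysosome, 8 fell by small amounts (adjusted p = 0.0195), such as vps-39 by 0.13 and vps-37 by 0.20. Of 14 nspc genes, which belong to the sperm list above, 9 rose with the nuclear extract (adjusted p = 0.000331), and of 91 unc genes, a class named for uncoordinated movement, 19 rose (adjusted p = 0.0453). These genes were named after their values were seen.

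On chromosome V, 3 neighbouring genes between 16926922 and 16930063 were higher with every diet. The pseudogene Y102A5C.5 rose by 2.06, 2.20 and 1.45 (edgeR adjusted p = 1.34e-05, 7.86e-06 and 0.000164) with desiccated thymus, the cytoplasmic extract and the nuclear extract. The pseudogene Y102A5C.6 rose by 2.01, 2.17 and 1.60, and the protein-coding gene Y102A5C.36 by 2.43, 2.52 and 2.00. The neighbours Y102A5C.2 and Y102A5C.4 did not pass in any of the 3 comparisons with edgeR. Reads shared between these neighbours were not tested.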
